A study of Mus musculus with 44 samples.

How the data were processed

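The series holds mRNA-seq of mouse plasma cells (CD138high B220-) sorted as YFP+ or YFP- from bone marrow and spleen. Young mice (6 to 8 weeks at tamoxifen) and middle-aged mice (24 weeks) were taken at day 90 after tamoxifen, and mice of 24 weeks at day 5. Per the labels, cDNA was made with SMART-Seq v4 and libraries with Nextera XT. The submitters' processing notes name STAR 2.6.1b, RSEM 1.3.1 and DESeq2 1.26.0 and both a GRCm39 and a GRCm38 build, with no role given for either. The deposited table holds expected counts per gene of the RSEM kind, not scaled between libraries, from which the authors left out immunoglobulin genes. In it 3.1% of the values are not whole; they were rounded.

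The table has 54960 gene rows and 44 libraries of 13 mice; 51684 row IDs are in GENCODE M21, 1362 rows have no gene name and 2 have immunoglobulin names. Groups were taken from the labels, with 3 or 4 libraries in each of 12 groups. In 1 library, the day-5 bone marrow library of mouse 09-15, the title (TOM, used for YFP- cells) contradicts the cell type label (LLPC, used for YFP+ cells); it is in no comparison. At day 90 there are 4 libraries per group, except 3 in each YFP+ group of young mice. At day 5 there are 3 per group, except 4 in the YFP+ spleen group. Titles name the mouse, by a name with an M or F prefix or by a date; a middle-aged and a young mouse are both called M2. The prefixes match the levels of Xist and of Y-linked genes in every library of those mice. Day-5 libraries of mouse 09-01 held Xist and nearly no Y-linked mRNA, and those of 07-26, 09-15 and 09-29 the reverse. Expression left after removing group means was more alike within a mouse (median r across genes 0.18 over 57 pairs of libraries) than between mice of a cohort (-0.06 over 175 pairs), so the mouse names pair the libraries; genes are not independent replicates.

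The column names also carry a day and month whose meaning is not stated. Libraries of 1 mouse share it, so the mouse block covers it. Too few mice share a date for values within dates of the age and time comparisons, and age and time are between mice.

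Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (minimum count 10; 12457 genes tested), 1 quasi-likelihood fit (robust) of 43 libraries with 1 mean per group, F tests of contrasts, Benjamini-Hochberg over the genes of each contrast and a threshold of 0.05. The common dispersion was 0.18 (coefficient of variation 0.425). Contrasts at day 90 average young and middle-aged mice with equal weight. The comparisons are YFP+ against YFP- by organ and day, bone marrow against spleen, day 90 against day 5 and middle-aged against young by sort and organ, and the difference of the YFP contrast between days, organs and ages. CPM are TMM-scaled; group values in the text are means ± SD of libraries. The mouse block (mouse as a fixed term) gives no value for contrasts between mice.

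Lists were tested with limma 3.58.1 camera on log CPM (prior count 2, preset correlation 0.01), adjusted over the 18 programme lists of a comparison, in 16 comparisons. The programme lists are plasma cell identity, B cell and antigen presentation, proliferation, unfolded protein response and ER secretion (called ER secretion), integrated stress response and amino acid (called stress response), apoptosis regulators, survival receptors and niche signals, homing and trafficking, plasma cell surface molecules, glycolysis and glucose uptake, nuclear oxidative phosphorylation (called the respiratory chain), mitochondrially encoded genes, autophagy and lysosome, immediate early and dissociation, NF-kB and TNF response, interferon response, ribosomal proteins and cholesterol synthesis. The lists for what else the sort could hold are T cell, NK cell, neutrophil and granulocyte precursor, monocyte and macrophage, erythroid, megakaryocyte and platelet, stromal and endothelial, plasmacytoid dendritic cell, and eosinophil, basophil and mast cell markers; these and the 5 sex-linked genes were not tested as lists. Some members of the surface, homing and survival lists may be genes the study itself reported on. Ccr9 is in a homing and a plasmacytoid list.

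The groups, comparisons, tests, lists, naming rule and other settings to try were fixed before the data were examined. The rule names, per comparison, up to 10 higher and 10 lower genes by p (3 each way for bone marrow against spleen at day 5 and for the difference contrasts) among those with an adjusted p under 0.05, at least a 2-fold change and a mean of at least 20 CPM in the higher group. Gene models without a descriptive symbol, pseudogenes, immunoglobulin genes, Y-linked genes and Xist are left out; members of the lists can be named with their values. Several list members that passed are not named in the text, and the result of 1 is not reported here.

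Those settings were DESeq2 size factors in edgeR, no filter (22324 genes), a stricter filter (5 CPM in 3 libraries; 9392 genes), the DESeq2 1.42.0 Wald test, limma voom with quality weights, a fit of the compared groups alone, the mouse block, F-prefixed mice alone, each library left out in turn, and for lists an estimated correlation and the fry rotation test. Runs without the 3 libraries under 200 CPM of Sdc1 and with Jchain left out of the table were added after the data were seen, as was the proliferation list of the day-5 marrow YFP contrast with each of its 6 libraries left out. For lists the mouse block was run at the preset correlation alone. The largest shift of all genes between scalings was 0.048 (log2).

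Depth was 6.64 to 12.66 M counts per library (median 9.59), with 12749 to 14200 genes at 1 count or more. Jchain took 19.9 to 46.2% of the counts and mitochondrially encoded genes 0.61 to 2.17%. Simulated data with this design and depth were used to test edgeR. In the marrow YFP contrast at day 90 it recovered 59.7% of genes changed by log2 1 and 85.1% by log2 2 (3 false among 174 calls). The values were 49.3% and 88.1% in that of spleen (10 false among 177) and 32.8% and 73.1% in marrow at day 5 (8 among 140). For the difference between days in spleen edgeR recovered 11.9% and 52.2% (4 false among 104). With simulated mouse effects (SD 0.3), it recovered 6.0% and 68.7% in the day-5 spleen contrast. Libraries are not stated to be stranded, so counts of overlapping genes on opposite strands are not parted. The self-made lists and 1 gene annotation are the only other inputs; no reads were realigned.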

Results

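Plasma cells (CD138high B220-) of bone marrow and spleen were sorted into cells that carry a tamoxifen-induced YFP mark (YFP+, labelled LLPC) and cells that do not (YFP-, labelled Bulk PC). They came from mice at day 5 or day 90 after tamoxifen. Replicates are separate mice, and most mice gave a YFP+ and a YFP- library of both organs. Among young mice only F2 and F9 did so. Their YFP+ libraries come from F2, F7 and F9, and their YFP- libraries from F2, F9, M2 and M7. The young part of the YFP contrasts thus mixes sort with the M and F prefixes. The YFP contrasts were not run in F-prefixed mice alone. Levels are CPM of the deposited counts, which hold no immunoglobulin genes, as mean ± SD. Changes are log2 ± SE from 1 edgeR fit of all assigned libraries, and passing means an adjusted p under 0.05.

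At day 90, YFP+ plasma cells of the bone marrow held less mRNA of 3 class II chains and of several surface receptors than YFP- cells (7 YFP+ and 8 YFP- libraries, young and middle-aged mice weighted equally). Slamf6, a SLAM-family receptor of lymphocytes, fell from 129 ± 25.6 to 33.7 ± 10.2 CPM (log2 change -2.04 ± 0.20, adjusted p = 9.96e-09). The class II chains H2-Ab1 (1041 ± 183 to 457 ± 92.3 CPM), H2-Aa (181 ± 45.3 to 51.7 ± 19.9) and H2-Eb1 (281 ± 34.8 to 161 ± 36.1) also fell, with log2 changes of -1.23 ± 0.14, -1.87 ± 0.29 and -0.84 ± 0.12. The more abundant invariant chain Cd74 did not pass (16516 ± 3813 against 20118 ± 5041 CPM, -0.27 ± 0.25), nor did it in spleen (18055 ± 4118 against 14974 ± 3178, 0.28 ± 0.25). Lower as well were Fam3c, a secreted cytokine-like protein (-2.64 ± 0.29, from 58.3 ± 18.7 to 9.75 ± 5.4 CPM), the chemokine receptor Cxcr3 (-2.25 ± 0.35) and the inhibitory receptor Tigit (-2.24 ± 0.39). The NAD-consuming ectoenzyme Cd38 fell from 20.3 ± 7.16 to 6.47 ± 3.57 CPM (-1.68 ± 0.22). Gsto1, a glutathione transferase (-1.51 ± 0.28), Rcn3, a calcium-binding protein of the ER (-1.17 ± 0.17), and Fxyd5, a regulator of the sodium pump (-1.02 ± 0.17), complete the lower genes that the naming rule takes. The Rcn3 change lay mostly in young mice, with 6.4 ± 1.04 CPM in YFP+ cells. Middle-aged YFP+ libraries held 16.7 to 26.8 CPM, which overlaps the 19.5 to 40 of YFP- libraries.

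In the same marrow, Rab3b, a small GTPase of secretory vesicles, rose from 24.5 ± 5.51 to 49.3 ± 7.63 CPM (1.00 ± 0.15, adjusted p = 0.000128). Spag6, a protein of sperm flagella with a close paralog, rose from 19.2 ± 6.73 to 54.2 ± 14.3 CPM (1.49 ± 0.32), as did the glutathione transferase Gstm1 (1.05 ± 0.21) and the gut-homing chemokine receptor Ccr9 (1.64 ± 0.37, 6.71 ± 3.54 to 20.3 ± 6.72 CPM). Sharing of reads with paralogs was not tested for Spag6 and Gstm1. In all, 14 genes were higher and 43 lower in YFP+ cells, out of 12457 tested. With mouse as a block 120 passed, 51 of the 57 among them. The Ccr9 call ended in 5 of the 15 fits that left out 1 library (adjusted p = 0.0705 without the YFP+ library of young mouse F9, and 0.051 without the 3 libraries lowest in Sdc1). Gstm1 ended without the same F9 library (0.0827) and Spag6 without the YFP+ library of young mouse F2 (0.0566).

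By gene list, 4 of the 22 measured B cell and antigen presentation genes fell in the marrow, and none rose; the 3 class II chains were among them. Adjusted over the list alone, 6 fell. The list's median was -0.40 and its test passed (camera adjusted p = 2.82e-07), as it did with an estimated correlation (adjusted p = 0.0177). Without the 3 libraries lowest in Sdc1 that last value was 0.0607. None of the 32 proliferation genes passed in the marrow (8 fell adjusted over the list alone, Cdk1 and Aurkb among them). The list as a whole lay lower (median -0.89, adjusted p = 1.9e-12, and adjusted p = 0.166 with an estimated correlation). The ER secretion list was lower (median -0.22, 26 of 32 genes negative, adjusted p = 0.01; 0.112 with mouse as a block, and adjusted p = 0.225 with an estimated correlation), with no member passing. The stress response and amino acid list was higher (median 0.18, 16 of 19 genes positive, adjusted p = 0.00742, and adjusted p = 0.533 with an estimated correlation; 0.0577 without the 3 libraries lowest in Sdc1).

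In the marrow the plasma cell transcription factors Prdm1 (-0.15 ± 0.20), Irf4 (0.26 ± 0.21) and Xbp1 (-0.21 ± 0.13) did not pass, nor did the CD138 gene Sdc1 (0.08 ± 0.23), the BCMA gene Tnfrsf17 (410 ± 68.1 against 456 ± 57.9 CPM) and Cd28 (230 ± 61.6 against 229 ± 65.8 CPM). The survival factors Mcl1 (0.10 ± 0.14) and Bcl2 (0.51 ± 0.19) did not pass either. Of 17 survival receptors, 1 rose, Cd93, a surface glycoprotein of long-lived plasma cells (0.85 ± 0.18, 57.8 ± 20.9 to 99.8 ± 29 CPM), and Cd38 fell. Adjusted over the list alone, 2 rose and 1 fell. The Cd93 call ended without the YFP+ library of young mouse F2 (adjusted p = 0.0607). Of 31 homing genes, Ccr9 rose, Cxcr3 fell and S1pr1, the sphingosine phosphate receptor of tissue egress, fell from 3.83 ± 3.54 to 0.0362 ± 0.0621 CPM (1 rose and 3 fell adjusted over the list alone). S1pr1 did not pass in voom (adjusted p = 0.113). Of 28 surface molecules, Cd93 rose, and Tigit and the complement regulator Cd55 fell (Cd55 -0.88 ± 0.15; 1 rose and 3 fell adjusted over the list alone). Of 19 apoptosis regulators, the death receptor Fas fell (-0.97 ± 0.18, 1 adjusted over the list alone). Of 24 autophagy and lysosome genes the protease Ctsl rose (0.59 ± 0.13, 1 adjusted over the list alone, 0.0579 without the YFP+ library of F9 and 0.123 in a fit of the compared groups alone). With mouse as a block and the preset correlation, the plasma cell identity list was lower (adjusted p = 0.0129, against 0.221) and so was cholesterol synthesis (0.04, against 0.297). An estimated correlation, in the fit without the block and without the 3 libraries lowest in Sdc1, gave adjusted p = 0.323 and 0.799.

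In the spleen at day 90 more genes passed than in the marrow: 143 were higher and 297 lower in YFP+ cells (7 YFP+ and 8 YFP- libraries). No gene passed when the YFP difference was compared directly between organs (smallest edgeR adjusted p 0.144, 11 genes with mouse as a block). Slamf6 fell from 133 ± 45.3 to 14.4 ± 7.38 CPM (-3.31 ± 0.21, adjusted p = 1.67e-14), H2-Ab1 from 1324 ± 328 to 428 ± 54.1 (-1.65 ± 0.14), H2-Eb1 from 286 ± 38.8 to 112 ± 27.5 (-1.40 ± 0.12) and Fas from 65.3 ± 14.6 to 23.1 ± 5.44 (-1.53 ± 0.18). Fam3c (-3.31 ± 0.30), Cxcr3 (-3.48 ± 0.38), Rcn3 (-1.40 ± 0.17) and Fxyd5 (-1.51 ± 0.18) fell as in the marrow. So did Prss57, a serine protease of granulocytes (-4.73 ± 0.47, 31.7 ± 18.5 to 1.34 ± 1.12 CPM), and Gpx3, a secreted glutathione peroxidase (-2.77 ± 0.34, 30.2 ± 13.4 to 4.28 ± 1.92 CPM). Rcn3 in YFP+ spleen cells was at 22 ± 7.3 CPM in middle-aged and 9.07 ± 1.78 in young mice, against 37.4 ± 6.51 in YFP- cells.

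Higher in YFP+ spleen cells were Spag6 (6.38 ± 2.59 to 44.1 ± 5.47 CPM, 2.79 ± 0.33), Rab3b (25.1 ± 5.81 to 60.4 ± 11.7, 1.27 ± 0.15), the iron carrier Trf (77.2 ± 11.2 to 173 ± 30.4, 1.14 ± 0.15) and the small heat shock protein Hspb1 (9.11 ± 3.96 to 34.7 ± 8.29, 1.99 ± 0.27). The others that the rule takes are the ER-anchored transcription factor Creb3l1 (1.19 ± 0.17), Cd93 (1.14 ± 0.18, 41.9 ± 16.4 to 89 ± 30.1 CPM), the lipase Mgll (1.44 ± 0.25), the metallothionein Mt2 (1.80 ± 0.31), Ly6i (1.84 ± 0.32) and Ptov1 (1.67 ± 0.31). Each of these 20 spleen genes passed in every fit that left out 1 library. Sharing of reads with paralogs was not tested for Mt2, Ly6i and Spag6. With mouse as a block 746 genes passed, 392 of the 440 among them. Without the YFP+ library of young mouse F9 the count was 286.

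Cell cycle genes fell in YFP+ spleen cells: 14 of 32 proliferation genes were lower and none higher (23 lower adjusted over the list alone). Cdk1, the mitotic kinase, fell from 12.6 ± 9.13 to 0.949 ± 0.795 CPM (-3.64 ± 0.67), Aurkb from 8.51 ± 6.29 to 0.661 ± 0.465 (-3.96 ± 0.67) and Ube2c from 23.8 ± 29.7 to 0.522 ± 0.527 (-5.14 ± 1.08). The list passed (median -1.41, adjusted p = 1.74e-14), but not with an estimated correlation (adjusted p = 0.134). Markers of other cells moved the same way: the neutrophil and precursor list had a median of -2.44 (summed 46.9 ± 36.3 in YFP+ against 98.2 ± 99.1 CPM in YFP- cells of middle-aged mice, and 13.3 ± 17.4 against 245 ± 292 in young mice) and the NK list one of -1.71. Mki67, the proliferation antigen, passed at 19.3 ± 4.97 against 38.1 ± 16 CPM (-0.93 ± 0.26, adjusted p = 0.0363). That call ended in 10 of the 15 fits that left out 1 library (up to 0.129, without the YFP- library of middle-aged mouse M2). With mouse as a block, 15 of the list passed, without Ccnb1 (adjusted p = 0.172) and Aurka (0.225).

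Cholesterol synthesis genes fell as well, 5 of 21 (8 adjusted over the list alone): Idi1 (17.7 ± 7.23 to 6.28 ± 1.94 CPM, -1.52 ± 0.28), Sqle, the squalene epoxidase (19.7 ± 7.5 to 7.54 ± 3.95, -1.43 ± 0.33), Fdft1, the squalene synthase (-0.59 ± 0.14), Fdps and Cyp51. The list's median was -0.46 (adjusted p = 0.000193, and adjusted p = 0.134 with an estimated correlation). Of 31 homing genes 5 fell: Cxcr3, S1pr1 (13.2 ± 9.2 to 1.09 ± 1.52 CPM), the transcription factor Klf2, Cd44 and the integrin Itgam (18.3 ± 13.3 to 0.604 ± 0.482 CPM). The atypical chemokine receptor Ackr3 rose (1.79 ± 0.39). Adjusted over the list alone, 3 rose and 8 fell. The list was lower (median -0.35, -0.07 in voom, adjusted p = 0.0206, and adjusted p = 0.154 with an estimated correlation). The Cd44 call ended without the YFP- library of middle-aged mouse M2 (0.0837) and the Klf2 call without the YFP+ library of young mouse F7 (0.0854), each the highest of several such values. Fdps (up to 0.0553, without the YFP+ library of young F7) and Cyp51 (up to 0.0689, without the YFP- library of middle-aged M3) ended in some fits too.

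Of the B cell and antigen presentation list 4 of 22 genes fell, the 3 class II chains again among them (7 adjusted over the list alone). Over the whole list 11 members were positive and 11 negative, the median was -0.03 (0.02 in voom) and the mean -0.38. The list test passed (adjusted p = 0.00502), but not with mouse as a block (0.175), nor with an estimated correlation (adjusted p = 0.154). Of 28 surface molecules 3 rose, among them Cd93, Ly6a (2786 ± 539 to 5039 ± 1031 CPM) and Ly6e (4859 ± 482 to 7047 ± 1381 CPM). Among the 4 that fell were Tigit (-2.75 ± 0.40), Cd48 (-1.06 ± 0.18) and Cd55 (-1.07 ± 0.15). Adjusted over the list alone, 8 rose and 5 fell (list adjusted p = 0.119, and 0.0401 with mouse as a block). Of 17 survival receptors, Cd93 and the BAFF receptor Tnfrsf13c (138 ± 40.9 to 223 ± 31 CPM) rose while Cd38 and Cd44 fell. Adjusted over the list alone 5 rose and 2 fell (list adjusted p = 0.0525). Tnfrsf17 (-0.20 ± 0.16), Cd28 (0.01 ± 0.18), Sdc1 (0.44 ± 0.23), Prdm1 (-0.08 ± 0.20), Irf4 (0.11 ± 0.21) and Xbp1 (-0.07 ± 0.13) did not pass, nor did Mcl1 (0.01 ± 0.14) and Bcl2 (0.43 ± 0.19). The bone marrow retention receptor Cxcr4 (0.50 ± 0.40) and the mucosal chemokine receptor Ccr10 (-1.45 ± 0.45, adjusted p = 0.0646) did not pass, and both did with mouse as a block (0.00951 and 1.29e-05).

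Of 32 ER secretion genes the chaperone Hsp90b1 fell (-0.46 ± 0.12, 1 rose and 1 fell adjusted over the list alone). The list was lower (median -0.20, adjusted p = 0.0165, 0.0882 with mouse as a block, and adjusted p = 0.154 with an estimated correlation). The call of Hsp90b1 ended without the YFP+ library of young mouse F9 (adjusted p = 0.0698). The 13 mitochondrially encoded genes were lower as a list (median -0.33, adjusted p = 0.0206, and adjusted p = 0.45 with an estimated correlation), with no member passing. Without the 3 libraries lowest in Sdc1 that list had 0.139 (median -0.13). Ctsl, the lysosomal membrane protein Lamp1 and Wipi1 rose among 24 autophagy and lysosome genes (3 rose and 2 fell adjusted over the list alone, list adjusted p = 0.119). Among 31 interferon genes Isg15 and Samhd1 fell (2 adjusted over the list alone, list adjusted p = 0.586), and among 23 NF-kB genes Nfkbia and Ebi3 rose (2 adjusted over the list alone, 0.39). Among 38 nuclear respiratory chain genes Ndufa4 fell (1 adjusted over the list alone, 0.173). Among 18 identity genes Trp53inp1 fell (3 adjusted over the list alone, 0.12, and 0.0153 with mouse as a block). Of 19 apoptosis regulators Fas fell (2 adjusted over the list alone, 0.161). No member passed among ribosomal proteins (median -0.05, list adjusted p = 0.344), the stress response and amino acid list (0.18, 0.158), glycolysis (-0.04, 0.173, 5 fell adjusted over the list alone) or immediate early genes (0.20, 0.119, and 0.00475 with mouse as a block). The calls of Wipi1, Nfkbia, Ebi3, Ndufa4, Isg15 and Trp53inp1 each ended in at least 2 of the 15 fits that left out 1 library. The highest adjusted p were 0.0806 and 0.157 (both without the YFP+ library of young F9), 0.0849 (YFP- library of young M7), 0.0827 (YFP- library of middle-aged M2), and 0.0631 and 0.111 (both YFP+ library of young F2).

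The genes that passed overlapped between organs and between cohorts. Bone marrow and spleen shared 10 higher genes (0.161 would be shared by independent draws) and 37 lower genes (1.03), and all 14 and 43 marrow calls had the same sign in spleen. The organs share mice, and 65.2% of all genes had the same sign. In spleen, young and middle-aged mice, which are independent mice, shared 8 higher (0.0488) and 39 lower genes (0.54), out of 32 and 83 in young and 19 and 81 in middle-aged mice. In marrow they shared 3 lower genes (0.0124) of 11 in young and 14 in middle-aged mice, and none of the 1 higher gene in each.

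**Figure D1:**
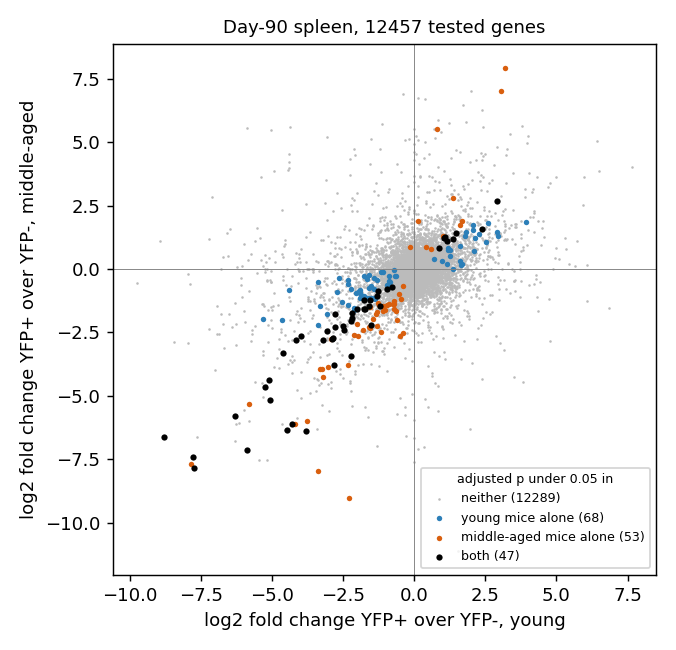
Log2 change of each of the 12457 genes tested between YFP+ and YFP- spleen cells at day 90 in young mice (x axis) and middle-aged mice (y axis), 1 point per gene, coloured by where it passed. The 47 genes that passed in both cohorts lie in the corners where both changes have 1 sign; 68 passed in young mice alone, 53 in middle-aged mice alone and 12289 in neither.

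**Figure D2:**
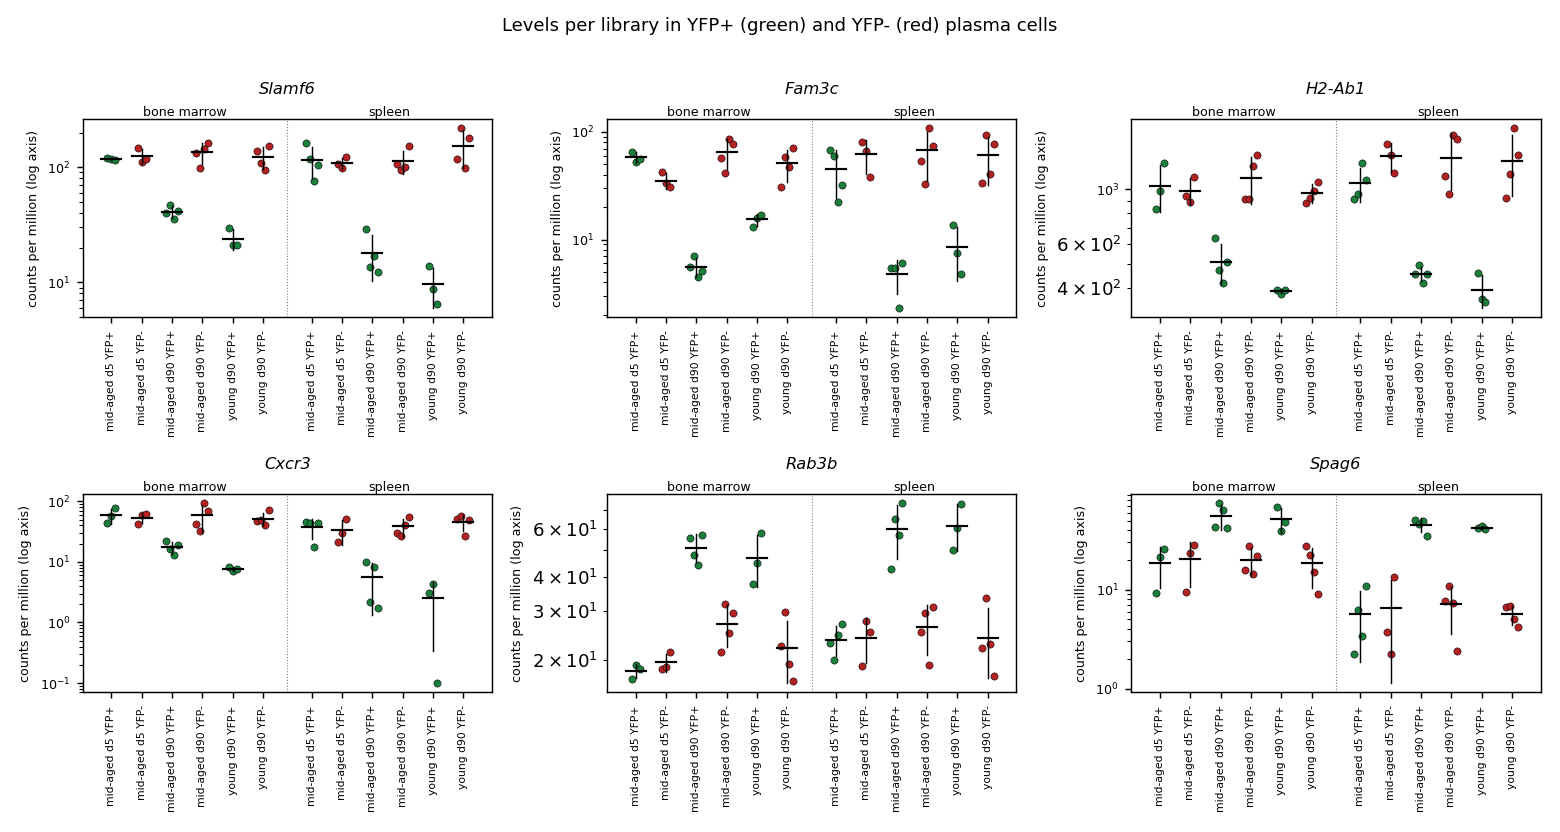
CPM (log axis) of Slamf6, Fam3c, H2-Ab1, Cxcr3, Rab3b and Spag6 in each library of the 12 groups; points are mice, bars mean ± SD, and lower bars end at 0.5 of the lowest point where mean - SD lies under that. Slamf6 stands at 115 ± 35 in YFP+ spleen cells at day 5 and at 18 ± 7.77 at day 90 in middle-aged mice, against 109 ± 12 and 113 ± 26.2 in YFP- cells.

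At day 5 none of the genes named for day 90 passed between YFP+ and YFP- cells in the fit without mouse as a block. Slamf6 was at 118 ± 2.66 CPM in YFP+ and 126 ± 19.4 in YFP- marrow cells (log2 difference -0.09 ± 0.29, 3 and 3 libraries). In spleen it was at 115 ± 35 and 109 ± 12 (0.08 ± 0.27, 4 and 3 libraries). H2-Ab1 differed by 0.06 ± 0.21 in marrow and -0.36 ± 0.20 in spleen, and Fam3c by 0.71 ± 0.41 and -0.45 ± 0.38. These were, with mouse as a block, -0.08 ± 0.26 and 0.21 ± 0.26 for Slamf6, 0.06 ± 0.20 and -0.48 ± 0.20 for H2-Ab1 (spleen adjusted p = 0.116), and 0.73 ± 0.37 and -0.22 ± 0.37 for Fam3c. None of the genes that the rule takes at day 90 passed at day 5 in the same organ with the block, while in spleen Ube2c (0.044), Cox6a2 (0.0352) and Xbp1 (0.044) did. No gene passed in marrow by edgeR (smallest adjusted p 1, 254 genes at an unadjusted p under 0.05, 2 with mouse as a block, DESeq2 5, voom 0). None passed in spleen (smallest 0.163, 1865 unadjusted, 456 with mouse as a block, DESeq2 35, voom 1817). Without the YFP- spleen library of mouse 09-29 edgeR called 1694, and without that of mouse 09-01 it called 2.

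The marrow's proliferation list was already lower in YFP+ cells at day 5: 30 of 32 genes were negative (median -1.63, adjusted p = 4.44e-22, and adjusted p = 0.0401 with an estimated correlation). No member passed, and 6 fell adjusted over the list alone. Without the 3 libraries lowest in Sdc1 the estimated correlation gave 0.0892. The YFP- marrow library of 07-26 held 682.7 CPM of summed neutrophil and precursor markers (2.8 and 12.2 in the other YFP- libraries) and 713.2 of erythroid markers (9.6 and 12.5). Without it the list's median on log CPM went from -1.22 to -0.46 (adjusted p = 3.27e-07, and adjusted p = 0.468 with an estimated correlation), a test chosen after the values were seen. Only without the YFP- library of 09-29 did the list pass with an estimated correlation among the 6 left-out runs (adjusted p = 0.00519). The plasma cell identity list passed there only with mouse as a block (0.0132, against 0.121). Its estimated correlation, in the fit without the block and without the 3 libraries lowest in Sdc1, gave adjusted p = 0.468. Of 7 measured eosinophil, basophil and mast cell markers, 5 fell adjusted over the list alone, among them the basophil proteases Mcpt8 (0 ± 0 against 187 ± 324 CPM) and Prss34 (0.14 ± 0.243 against 746 ± 1291), whose spread comes from 1 YFP- library.

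In the spleen at day 5, all 34 ribosomal protein genes lay lower in YFP+ cells (median -0.65, 19 adjusted over the list alone, none over all genes; adjusted p = 2.03e-12, and adjusted p = 0.738 with an estimated correlation). The mitochondrially encoded genes (median -0.79, 7 adjusted over the list alone, adjusted p = 0.00015) and nuclear respiratory chain genes (median -0.53, adjusted p = 0.00021) were lower as well, each with an adjusted p = 0.738 with an estimated correlation. Without the 3 libraries lowest in Sdc1, of which this contrast holds 1, the medians were -0.35 (ribosomal), -0.51 (mitochondrial) and -0.22 (respiratory chain). The ribosomal gap lay in mice 07-26 and 09-01. In mouse 09-29 the list's mean log2 level was 7.45 in YFP+ and 7.51 in YFP- cells. In the same contrast 11 of 17 macrophage markers fell adjusted over the list alone (median -3.84). The YFP- library of mouse 07-26 held 1873.8 CPM of summed macrophage markers against 346.3 and 550.5 in the other YFP- libraries, and the lowest Sdc1 of all (139.7 CPM). Without the 3 libraries lowest in Sdc1 the proliferation list passed too (adjusted p = 0.041, against 0.0592, and adjusted p = 0.809 with an estimated correlation), although its median shrank from -0.89 to -0.41.

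From day 5 to day 90, Slamf6, Fam3c and H2-Ab1 fell and Rab3b rose in YFP+ cells of middle-aged mice, in both organs. In marrow (4 libraries at day 90, 3 at day 5) Fam3c fell from 57.8 ± 6.85 to 5.57 ± 1.11 CPM (-3.37 ± 0.41), Cd38 from 26.8 ± 4.15 to 3.9 ± 1.03 (-2.78 ± 0.31) and Slamf6 from 118 ± 2.66 to 41 ± 4.94 (-1.52 ± 0.27), while Rab3b rose from 18.3 ± 1.02 to 51.2 ± 6.1 (1.48 ± 0.23). In all 4 genes rose and 13 fell. The rule also takes Mt2 (2.18 ± 0.48), H2-Ab1 (-1.02 ± 0.20), the spermine synthase Sms (-1.09 ± 0.24), Sqle (-2.16 ± 0.47), the cyclin Ccng2 (-1.06 ± 0.23), Cyb561a3 (-1.11 ± 0.25) and Fam107b (-1.01 ± 0.22). Each of these 7 ended in at least 5 of the 7 fits that left out 1 library (highest adjusted p = 0.353, without the day-5 YFP+ library of mouse 09-01). For H2-Ab1 the highest was 0.152, without that of mouse 09-29. The count fell to 8 without the day-5 library of mouse 07-26, to 7 without that of 09-01, and to 10, 10 and 8 without the day-90 libraries of F12, M2 and M3.

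In spleen (4 and 4 libraries) 8 genes rose and 37 fell in YFP+ cells. Spag6 rose from 5.74 ± 3.9 to 45.4 ± 7.26 CPM (2.98 ± 0.47), Rab3b from 23.6 ± 2.92 to 59.7 ± 13.4 (1.34 ± 0.21), Trf from 81.2 ± 16.6 to 185 ± 33.5 (1.19 ± 0.21), Hspb1 (1.62 ± 0.37) and Tmem205 (1.15 ± 0.26). Slamf6 fell from 115 ± 35 to 18 ± 7.77 CPM (-2.67 ± 0.27), and H2-Ab1 from 1058 ± 165 to 456 ± 31.2 (-1.22 ± 0.19). Fam3c (-3.23 ± 0.40), Gpx3 (-3.13 ± 0.47), Prss57 (-3.80 ± 0.59), Cxcr3 (-2.78 ± 0.48) and the class II chain H2-Ob (-1.94 ± 0.36) fell too, as did the cytokinesis gene Prc1 (-2.52 ± 0.50), Tigit (-2.62 ± 0.53) and the DNA repair gene Fanca (-1.50 ± 0.31). Single left-out libraries ended Hspb1 (up to 0.196, without the day-5 library of 07-26), and, without the day-90 library of M3, Tmem205 (0.317), Prc1 (0.0676), Tigit (0.0987) and Fanca (0.121). In a fit of the compared groups alone Cxcr3 (0.0872), H2-Ob (0.104), Tmem205 (0.242) and Fanca (0.207) did not pass. The count rose to 89 without the day-5 library of 09-15 and fell to 21 without 07-26 or 09-01, to 19 without F15, to 18 without M2 and to 13 without M3.

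Cholesterol synthesis was lower at day 90 in YFP+ cells of both organs. In spleen 19 of 21 genes were negative (median -0.68, adjusted p = 1.48e-06, and adjusted p = 0.0494 with an estimated correlation, which was 0.0792 without the 3 libraries lowest in Sdc1). Sqle passed there and 4 genes fell adjusted over the list alone. In marrow the median was -0.36, Sqle passed and 3 genes fell adjusted over the list alone (adjusted p = 0.000841, and adjusted p = 0.249 with an estimated correlation). The calls of Sqle each ended in 5 of the fits that left out 1 library (up to adjusted p = 0.28 in marrow, without mouse 09-01, and 0.33 in spleen, without the day-5 library of 07-26). The lysosomal protease Ctsl rose in both (marrow 0.97 ± 0.19, 62.2 ± 4.47 to 122 ± 8.47 CPM, adjusted p = 0.204 without mouse 09-01; spleen 0.94 ± 0.17, 0.0872 in a fit of the compared groups alone). The B cell and homing lists were lower in spleen (medians -0.15 and -0.39, -0.05 and -0.12 in voom, adjusted p = 0.00851 and 0.00975, each adjusted p = 0.224 with an estimated correlation). In each, 2 members fell over all genes and 5 adjusted over the list alone. Ribosomal proteins were higher in marrow YFP+ cells (median 0.61, adjusted p = 4.91e-13, and adjusted p = 0.502 with an estimated correlation) and in marrow YFP- cells (0.59, 3.19e-14, and adjusted p = 0.43 with an estimated correlation). In the YFP+ marrow contrast, 10 of 12 erythroid and 9 of 14 neutrophil markers rose adjusted over the list alone, with medians of 7.99 and 4.77.

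YFP- cells gave no passing gene between day 5 and day 90. In marrow (4 and 3 libraries) edgeR called none (1076 at an unadjusted p under 0.05, DESeq2 0, voom 0), with Slamf6 at 0.10 ± 0.27 and H2-Ab1 at 0.17 ± 0.20. In spleen it called none (523 unadjusted, DESeq2 5, voom 0, and 61 without the day-5 library of 09-29), with Slamf6 at 0.06 ± 0.27 and Fam3c at 0.12 ± 0.38. The nuclear respiratory chain was higher at day 90 in marrow (median 0.54, 15 genes adjusted over the list alone, adjusted p = 1.3e-08, and adjusted p = 0.428 with an estimated correlation). In spleen the interferon list was lower (median -0.30, adjusted p = 0.000764, and adjusted p = 0.459 with an estimated correlation), but not without the 3 libraries lowest in Sdc1 (median -0.11, 0.414). Ribosomal proteins were lower too (-0.30, 2.6e-05, and adjusted p = 0.667 with an estimated correlation).

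Tested directly, the YFP difference of middle-aged mice changed from day 5 to day 90. In marrow 2 genes passed, Fam3c (-4.26 ± 0.57, adjusted p = 5.97e-05) and Cd38 (-2.87 ± 0.43, 0.000436), and 6 passed with mouse as a block. In spleen 3 passed upward, Trf (1.86 ± 0.30), Creb3l1 (1.76 ± 0.33) and Blvrb, a biliverdin reductase (2.17 ± 0.46). Downward passed 4, Slamf6 (-2.73 ± 0.38, adjusted p = 0.000168), Fam3c (-3.35 ± 0.55), Gpx3 (-3.45 ± 0.65) and Prss57 (-4.05 ± 0.80, chosen after its values were seen). With mouse as a block 91 passed. The spleen count is unsteady: 121 without the YFP- day-5 library of 09-29, 12 without the YFP+ library of 09-15, 3 without the YFP- library of 07-26, and 4 without the YFP+ library of 07-26 or the YFP- library of M2. A fit of the compared groups alone called 0. Single left-out libraries ended Blvrb (up to 0.713), Gpx3 (0.0837), both without the YFP- library of 07-26, and Creb3l1 (0.0604, without the YFP+ library of 07-26).

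**Figure D3:**
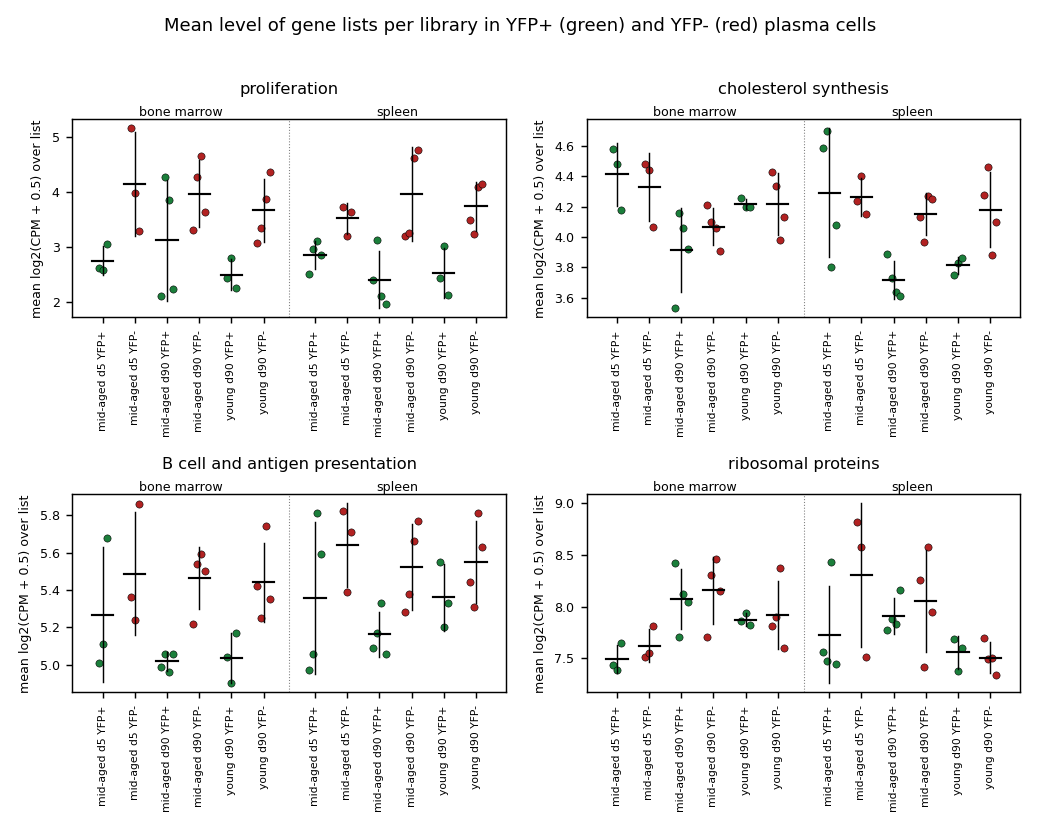
Mean log2(CPM + 0.5) of the proliferation, cholesterol synthesis, B cell and antigen presentation, and ribosomal protein lists in each library (y axis) of the 12 groups (x axis); points are mice, bars mean ± SD. In YFP+ spleen cells at day 90 proliferation genes sit lower than in YFP- cells (list median log2 change -1.41) and cholesterol synthesis genes too (-0.46).

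Between organs, Slpi, a secreted protease inhibitor, was higher in bone marrow than in spleen at day 90. In YFP- cells it stood at 18731 ± 10027 against 4466 ± 1552 CPM (2.12 ± 0.32, adjusted p = 0.00149, 8 and 8 libraries), and in YFP+ cells at 22595 ± 13889 against 7849 ± 5319 (1.60 ± 0.34, 0.033, 7 and 7 libraries). The YFP+ call ended in 9 of 14 fits that left out 1 library (up to 0.115, without the spleen library of young F7). Cd38 was lower in marrow in YFP+ cells (-1.34 ± 0.22) and in YFP- cells (-0.99 ± 0.19, up to 0.0675 without the marrow library of young mouse M2). YFP+ cells of the marrow kept more Slamf6 (33.7 ± 10.2 against 14.4 ± 7.38 CPM, 1.24 ± 0.20) and less Hspb1 (10.6 ± 3.62 against 34.7 ± 8.29, -1.71 ± 0.28) than those of the spleen. The adaptor Lime1 (1.47 ± 0.32), the adhesion receptor Cd2 (1.34 ± 0.31) and Fez2 (-1.05 ± 0.23) passed too, and each ended in at least 8 of the 14 such fits (up to 0.138 without the spleen library of young F2, and 0.202 and 0.137 without the marrow library of young F7). In YFP- cells Ica1 (1.11 ± 0.21), the metallothioneins Mt1 (1.38 ± 0.27) and Mt2 (1.40 ± 0.30), the CD43 gene Spn (-1.14 ± 0.24) and the interferon-induced GTPase Gbp6 (-1.72 ± 0.37) passed. All but Ica1 ended in some of these fits (up to 0.0756 for Mt1, 0.139 for Mt2 and 0.112 for Gbp6, without the marrow library of young M2, and 0.0959 for Spn, without the spleen library of middle-aged M2). Without the 3 libraries lowest in Sdc1, Ica1 (0.0567), Mt1 (0.155), Mt2 (0.162) and Spn (0.169) did not pass, and in a fit of the compared groups alone Gbp6 did not (0.25).

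In YFP+ cells 12 genes were higher and 12 lower in marrow (201 with mouse as a block, the 24 among them), and in YFP- cells 8 and 9 (124 with mouse as a block, the 17 among them). The YFP+ count fell to 14 without the spleen library of middle-aged F15, to 15, 12 and 10 without the marrow libraries of young F2, F7 and F9, and to 12 and 11 without the spleen libraries of young F2 and F9. The YFP- count was 4 without the 3 libraries lowest in Sdc1 and 29 without the marrow library of F12. It fell to 11 and 9 without the marrow libraries of middle-aged M2 and M3 and to 8 without the spleen library of M3. It also fell to 9, 10 and 6 without the marrow libraries of young F2, F9 and M2, and to 10 and 5 without the spleen libraries of young F2 and M7.

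Ribosomal proteins were higher in marrow than in spleen in YFP- cells (median 0.25, adjusted p = 3.96e-08, and adjusted p = 0.468 with an estimated correlation). They were higher in YFP+ cells too (0.26, and without the 3 libraries lowest in Sdc1 adjusted p = 8.47e-08, and adjusted p = 0.504 with an estimated correlation). Higher in YFP+ marrow cells were also mitochondrially encoded genes (0.36, adjusted p = 0.000109, and adjusted p = 0.324 with an estimated correlation), the respiratory chain (0.14, 0.00237, and adjusted p = 0.525 with an estimated correlation) and proliferation (0.30, 0.0121, and adjusted p = 0.576 with an estimated correlation). Survival receptors (-0.11, 0.0267, and adjusted p = 0.22 with an estimated correlation) and ER secretion genes (-0.06, 0.0295, and adjusted p = 0.324 with an estimated correlation) were lower. In YFP+ marrow libraries, the proliferation list's mean log2 level was 4.28 (middle-aged F15) and 3.85 (middle-aged M2), and 2.12 to 2.80 in the others. F15 and M2 held 3301.2 and 2704.6 CPM of summed erythroid markers there, against 12.6 to 56.9. Whether such RNA accounts for the proliferation list was not tested. In YFP- marrow cells the respiratory chain was higher (0.19, adjusted p = 0.00137, and adjusted p = 0.468 with an estimated correlation), and the ER secretion (-0.11, 0.0154, and adjusted p = 0.276 with an estimated correlation), homing (-0.27, 0.0169, and adjusted p = 0.276 with an estimated correlation) and stress response lists (-0.17, 0.0371, and adjusted p = 0.551 with an estimated correlation) were lower. The interferon list was lower in marrow in YFP+ and YFP- cells (-0.19, adjusted p = 0.00794, adjusted p = 0.324 with an estimated correlation, and -0.40, 0.00053, adjusted p = 0.276 with an estimated correlation). So were immediate early genes (-0.44, 0.000109, adjusted p = 0.288 with an estimated correlation, and -0.25, 0.0197, adjusted p = 0.468 with an estimated correlation). Cholesterol synthesis was higher in YFP+ marrow cells (0.30, adjusted p = 0.000109, and adjusted p = 0.22 with an estimated correlation). With mouse as a block the NF-kB list passed in YFP+ cells (0.0319, against 0.052) and the identity list in YFP- cells (0.0398, against 0.175). The estimated correlation, in the fit without the block and without the 3 libraries lowest in Sdc1, gave adjusted p = 0.439 and 0.533.

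Markers of other blood cells parted with the organs. Adjusted over the list alone, 10 of 14 neutrophil markers rose (median 3.77) and 8 of 17 macrophage markers fell (median -2.39) in YFP+ marrow against spleen. Over all genes Ly6g (3.69 ± 0.79) and Vcam1 (-5.15 ± 1.14) passed, and both calls ended in some fits that left out 1 library (up to 0.116 without the spleen library of young F9, and 0.19 without the marrow library of young F7). In YFP- cells 6 of 12 erythroid markers rose (median 3.92) and 6 of 13 T cell markers fell (median -1.73). Whether the YFP difference itself differed between organs was tested. No gene passed by edgeR (smallest adjusted p 0.144, 449 at an unadjusted p under 0.05, 11 with mouse as a block, DESeq2 8, voom 0), with Slamf6 at 1.28 ± 0.27. Left-out libraries gave 2 genes at most (2 without the YFP- spleen library of young M2, and 1 without the YFP+ libraries of F15 in marrow or F12 in spleen).

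At day 5 no gene passed between organs in YFP+ cells by edgeR (3 and 4 libraries, 298 at an unadjusted p under 0.05, 0 with mouse as a block, DESeq2 8, voom 0). In YFP- cells (3 and 3 libraries) 1 gene passed, the nuclear envelope gene Nemp1, named after its values were seen (1.29 ± 0.357 against 6.79 ± 3.55 CPM, -2.38 ± 0.44, adjusted p = 0.0444, 6 genes with mouse as a block). That count was 0 without any of the 3 marrow libraries or without the spleen libraries of 07-26 (Nemp1 at 0.859) or 09-01. It was 0 without the 3 libraries lowest in Sdc1, and 2023 without the spleen library of 09-29. The interferon list was lower in YFP+ marrow cells (median -0.63, adjusted p = 6.19e-05, and adjusted p = 0.276 with an estimated correlation). Ribosomal proteins were lower in YFP+ (-0.26, 6.19e-05, 0.883 with mouse as a block, and adjusted p = 0.751 with an estimated correlation) and in YFP- marrow cells (-0.84, 29 adjusted over the list alone, 9.24e-14, and adjusted p = 0.79 with an estimated correlation). In YFP+ cells the respiratory chain (0.0425, 0.867 with mouse as a block, and adjusted p = 0.751 with an estimated correlation) and ER secretion lists (0.0065, 0.0767 with mouse as a block, and adjusted p = 0.276 with an estimated correlation) passed, and the stress response list only with mouse as a block (0.0429, against 0.251). In YFP- cells the ER secretion list passed without the 3 libraries lowest in Sdc1 (0.00178, against 0.23, and adjusted p = 0.635 with an estimated correlation). In the YFP- contrast 13 macrophage markers fell and 6 neutrophil markers rose adjusted over the list alone (medians -5.05 and 7.11).

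Between cohorts at day 90, Rcn3 was higher in YFP+ cells of middle-aged than of young mice, in marrow (21.9 ± 4.39 against 6.4 ± 1.04 CPM, 1.77 ± 0.25, adjusted p = 0.000292) and in spleen (22 ± 7.3 against 9.07 ± 1.78, 1.27 ± 0.25, 0.0335, 4 and 3 libraries each). The gene model C130026I21Rik was higher in both (1.74 ± 0.26 and 1.59 ± 0.26), the peptidase Dpp4 was lower in marrow (0.419 ± 0.67 against 8.7 ± 3.02 CPM). In spleen the tetraspanin Tspan32 was lower (88.6 ± 16 against 178 ± 16.2 CPM) and the uroplakin Upk3a higher (2.64 ± 0.51). C130026I21Rik, Dpp4 and Upk3a lie outside the naming rule and were chosen after their values were seen. The young mice with YFP+ libraries all have F-prefixed names, so age and sex are mixed in the contrasts of all mice. F-prefixed mice alone (middle-aged F12 and F15 against young F2, F7 and F9) part age from sex, with fewer libraries. With F-prefixed mice alone, Rcn3 did not pass in marrow (adjusted p = 0.0643) or spleen (0.8), nor did Dpp4 (0.18), Tspan32 (0.315) and Upk3a, while C130026I21Rik passed in both organs. The marrow count of 3 was 5 without the YFP+ library of M2. In spleen the count of 4 was 0 without young F2 or F9, 1 without young F7, and 2 without middle-aged F12 or M2 (Rcn3 up to 0.479, Tspan32 0.462, both without F9, Upk3a 0.486 without F2, C130026I21Rik 0.171 without F9).

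YFP- cells gave no passing gene between cohorts by edgeR in marrow (4 and 4 libraries, 364 at an unadjusted p under 0.05, DESeq2 0, voom 0) or in spleen (4 and 4, 1634 unadjusted, DESeq2 29, voom 6). The spleen count was 275 without the library of middle-aged F15 and 5 without that of M3. The mitochondrially encoded genes were higher in middle-aged spleen cells, YFP- (median 1.11, 9 rose and 1 fell adjusted over the list alone, adjusted p = 1.46e-10, and adjusted p = 0.168 with an estimated correlation) and YFP+ (0.78, 2 adjusted over the list alone, 9.97e-10, and adjusted p = 0.101 with an estimated correlation). Ribosomal proteins were higher too, YFP- (0.63, 29 adjusted over the list alone, 3.23e-13, and adjusted p = 0.685 with an estimated correlation) and YFP+ (0.34, 9.08e-08, and adjusted p = 0.454 with an estimated correlation). The stress response list was lower in YFP+ spleen cells (-0.52, adjusted p = 1.08e-05, and adjusted p = 0.231 with an estimated correlation). In YFP+ marrow cells the proliferation list was higher in middle-aged mice (0.83, 0.00697, and adjusted p = 0.498 with an estimated correlation) and the survival receptor list lower (-0.29, 0.0129, and adjusted p = 0.155 with an estimated correlation). There 10 of 12 erythroid markers rose adjusted over the list alone (median 6.51). Middle-aged F15 and M2, with mean log2 proliferation levels of 4.28 and 3.85, held 3301.2 and 2704.6 CPM of summed erythroid markers. F12 and M3 had levels of 2.12 and 2.24, with 16.0 and 56.9 CPM, and the young mice levels of 2.25 to 2.80. Whether the YFP difference differs with age was tested in marrow (no gene by edgeR, 334 at an unadjusted p under 0.05, 6 with mouse as a block, DESeq2 5, voom 0, and 1 without the YFP+ library of F15). In spleen no gene passed either (414 unadjusted, 0 with mouse as a block, DESeq2 3, voom 0).

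Transcripts of other blood cells varied between libraries. Summed marker levels ran from 7.9 to 99.9 CPM for T cells, 4.6 to 114 for NK cells and 0.5 to 3082 for neutrophils and their precursors. They ran from 192 to 2396 for macrophages, 6.6 to 3301 for erythroid cells, 0 to 2.7 for megakaryocytes and 9.1 to 40.2 for stromal and endothelial cells. Plasmacytoid dendritic cell markers (1803 to 4448 CPM) and the eosinophil, basophil and mast cell list (466.3 to 4100 CPM) stood high in every library. Between YFP+ and YFP- spleen cells at day 90, Gzma of the NK list fell (39 ± 25 to 5.27 ± 3.67 CPM, -2.94 ± 0.55), as did Ly6g of the neutrophil list, whose median was -2.44 (6 of 14 fell adjusted over the list alone). The Ly6g call ended in 6 of 15 fits that left out 1 library (up to 0.108, without the YFP+ library of young F7). Cox6a2 (1.51 ± 0.38) of the plasmacytoid list and the eosinophil granule gene Prg2 (844 ± 206 to 2044 ± 633 CPM) rose. Summed NK markers stood at 17.4 ± 12 CPM in YFP+ and 60.8 ± 30.3 in YFP- spleen cells of middle-aged mice, and at 9 ± 6.37 and 58.4 ± 34 in young mice. The sums of the eosinophil, basophil and mast cell list, most of them Prg2, were 2268 ± 627 and 916 ± 54.7, and 2101 ± 468 and 833 ± 333. Those of the plasmacytoid list were 3440 ± 591 and 2334 ± 470, and 3409 ± 420 and 2038 ± 115. The sums were not tested. No T cell, macrophage, erythroid, megakaryocyte or stromal marker passed. The 5 sex-linked genes, which follow the mix of mice, did not pass in either organ (spleen list median -3.91).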

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

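The tests without the libraries lowest in Sdc1 were chosen after the counts of called genes had been seen; the other tests named here were written before their results. For 355 sets of 4 to 10 values, the gap from the highest or lowest library to its neighbour was compared with the range of its group, and 40 values stood apart, several of them from the same library; chance alone sets apart about 1 in 20 groups. These are day-90 libraries unless stated.

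YFP+ and YFP- spleen cells at day 90 differed in 440 genes, with a median size of change of 1.40 (log2, median SE 0.30). Removing each library's trend with transcript length left 418 of them past the threshold, at the same median size, and leaving out the libraries lowest in Sdc1 left 346 (median 1.33, SE 0.29); both argue against these as the whole source. With the summed neutrophil, macrophage and erythroid markers as covariates 276 stayed (median 1.39, SE 0.34). The size held while the error grew, which argues against RNA of these 3 kinds of cell as the whole source. It leaves it open for single genes such as Ly6g. Prss57 ran against the neutrophil sums in YFP+ spleen cells of middle-aged mice. It stood at 24.9 ± 12.8 CPM at day 5 with sums of 2.58 ± 2.5, and at 1.77 ± 1.36 at day 90 with 46.9 ± 36.3. For Prss57 this argues against neutrophil RNA as the source. NK, plasmacytoid and eosinophil, basophil and mast cell markers, whose sums differ between the sorts, were not covariates, so RNA of such cells stays open. A biological difference between marked and unmarked cells, which the design names, stays open as untested against it.

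Bone marrow and spleen differed at day 90 in 24 genes in YFP+ cells (median size 1.90, SE 0.38) and 17 in YFP- cells (1.14, SE 0.24). With the summed neutrophil, macrophage and erythroid markers as covariates 15 and 10 stayed (median 2.03, SE 0.44, and 1.08, SE 0.26), against RNA of these 3 kinds of cell as the whole source. T cell, NK and other markers were not covariates, so RNA of those cells stays open. In YFP+ cells 21 stayed without the libraries lowest in Sdc1. In YFP- cells 4 of 17 stayed without them (median 1.12, SE 0.25), and the part those libraries play cannot be told apart: leaving out both YFP- libraries of another mouse kept 16 (F12), 11 (F15) or 1 (M3). The organ itself stays open as untested against these.

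All 34 ribosomal protein genes lay lower in YFP+ than YFP- spleen cells at day 5 (median -0.65). The list's mean log2 level in YFP+ and YFP- cells was 7.56 and 8.82 in mouse 07-26 and 7.47 and 8.58 in 09-01. In 09-29 it was 7.45 and 7.51, and the YFP+ library of 09-15 stood at 8.43. Of 1000 lists matched in length and level, the median was -0.19 (from -0.34 to -0.05 for the central 95%), and after removal of the length trend the list stood at -0.56, which argues against length. Without the YFP- library of 07-26, lowest in Sdc1, the median was -0.35; the median SE of a member is 0.27, so its share cannot be told apart. That reading was settled after the value was seen. The YFP- library of 09-01 and the YFP+ library of 09-15, both high in the list, stayed in that run. They held 321.3 and 317.4 CPM of Sdc1, against 624.5 to 1032.8 in the other libraries kept. No biological explanation was tested.

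Differences between groups passed their own tests in middle-aged mice between day 5 and day 90. In marrow 2 genes did so, Fam3c (-4.26) and Cd38 (-2.87), and in spleen 7, with Trf at 1.86, Creb3l1 at 1.76, Blvrb at 2.17, Slamf6 at -2.73, Fam3c at -3.35 and Gpx3 at -3.45 (log2 differences of the YFP contrast). A signal outside the comparisons came from the library with contradictory labels, where Slamf6 was at 73.8 CPM.

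Single libraries stood apart in summed markers of other cells (CPM; the other libraries of the group in brackets). For neutrophils these were the day-5 YFP+ spleen library of 09-29 at 6.3 (0.9 to 1.6), the YFP+ marrow library of middle-aged M2 at 3081.6 (249 to 642) and the YFP- marrow library of young M7 at 844.9 (23.8 to 47.3). For erythroid cells they were the day-5 YFP+ spleen library of 09-15 at 470.9 (10.1 to 17.9), the YFP+ spleen library of M3 at 3098.0 (7 to 394) and the YFP- marrow library of young M2 at 674.9 (9.3 to 122). The YFP+ marrow library of middle-aged M2 also stood at 2395.6 for macrophages (751 to 870), the YFP- marrow library of F12 at 1967.7 for plasmacytoid dendritic cells (2618 to 2667), and the YFP- spleen library of young M7 at 1.1 for megakaryocytes (0.5 to 0.6). Mitochondrially encoded counts were 1.05% in the YFP- marrow library of F15 (0.98 to 0.98) and 1.01% in the YFP+ spleen library of M2 (1.11 to 1.13). Sdc1 was 830.9 CPM in the YFP- spleen library of young F2 (498 to 522).

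Among named genes, the same libraries recur (CPM). The YFP+ libraries of middle-aged F12 held Fxyd5 at 149 in marrow (56.1 to 87.2 in the others), Lime1 at 67.1 in marrow (19.2 to 38.6) and 24.3 in spleen (5.9 to 11.6), and Cd2 at 67.9 (6.43 to 18.8) and 20 (3.25 to 8.01). In spleen they held Hspb1 at 26.4 (37.7 to 39.9), Tigit at 10.4 (5.86 to 6.37 among middle-aged mice and 3.84 to 6.37 in both cohorts), Sqle at 16 (5.79 to 6.82 and 3.6 to 7.33) and Gzma at 13.3 (2.25 to 5.55). The YFP- libraries of middle-aged M2 held Fxyd5 at 242 in marrow (108 to 170) and 316 in spleen (134 to 209), and in spleen Itgam at 46.6 (3.61 to 21.9), Cd48 at 608 (206 to 375) and Ndufa4 at 694 (130 to 318).

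The YFP+ libraries of M3 held Slpi at 52920 in marrow (10712 to 22294) and 19240 in spleen (3569 to 9242), Ndufa4 at 202 in spleen (87.9 to 133) and S1pr1 at 0.137 in marrow (0 to 0 in the other middle-aged mice). Those of F15 held Mt2 at 66.9 in spleen (26.6 to 39.3), and in marrow Mki67 at 41.7 (11.3 to 24.3), Ly6g at 8.73 (0.456 to 3.7) and Dpp4 at 1.42 (0 to 0.137). Fam3c was 2.29 in the YFP+ spleen library of M2 (5.44 to 5.99), Cxcr3 17.4 in the day-5 YFP+ spleen library of 09-15 (44.3 to 45.9), Gpx3 59.4 in the YFP- spleen library of young F9 (17.3 to 35.8) and Ebi3 48.2 in that of young M2 (16.3 to 31.2).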

How the results depend on the processing

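The runs without the libraries lowest in Sdc1, without Jchain and of the proliferation list with day-5 marrow libraries left out were chosen after the data were seen; the other alternatives were planned. No single gene recomputed that had passed in the edgeR fit of all assigned libraries reversed its direction in any alternative. Genes that had not passed there were not counted for this. The balance of higher and lower genes turned with mouse as a block for organs in YFP- cells at day 90 (8 and 9 to 64 and 60) and day 5 (0 and 1 to 4 and 2) and for the difference between days in spleen (3 and 4 to 49 and 42). It also turned in voom for age in YFP+ spleen cells (3 and 1 to 7 and 26) and in DESeq2 for days in YFP+ marrow cells (4 and 13 to 69 and 64), and for some of these in further alternatives. Counts of passing genes depended on the test, and the cause was not tested. In the simulated marrow YFP contrast at day 90, DESeq2 made 20 false calls among 203. There edgeR made 3 among 174 and voom 4 among 172. DESeq2 and voom were simulated in that contrast alone, and in that of spleen edgeR made 10 among 177. DESeq2 gave for YFP+ against YFP- cells 132 (marrow, day 90, against 57), 663 (spleen, day 90, against 440), 5 (marrow, day 5) and 35 (spleen, day 5). For marrow against spleen it gave 96 and 67 (day 90, YFP+ and YFP-) and 8 and 215 (day 5), and for day 90 against day 5 133 (YFP+ marrow), 108 (YFP+ spleen) and 5 (YFP- spleen). For age it gave 20 (YFP+ marrow), 18 (YFP+ spleen) and 29 (YFP- spleen), and for the difference of the YFP contrast 11 and 39 (days, marrow and spleen), 8 (organs), 5 and 3 (ages). Voom gave 993 (YFP contrast, spleen, day 90), 1817 (the same at day 5), 202, 26 and 1793 (organs: YFP+ and YFP- at day 90, YFP- at day 5), 347 and 265 (days, YFP+ marrow and spleen). For age it gave 6, 33 and 6 (YFP+ marrow, YFP+ spleen, YFP- spleen), and 20 (difference between days, spleen). The mouse block gave 120 and 746 (YFP contrast, day 90), 2 and 456 (day 5), 201, 124 and 6 (organs: YFP+ and YFP- at day 90, YFP- at day 5), 6 and 91 (difference between days), 11 (organs) and 6 (ages, marrow). The list calls it changed stand in the report; of gene calls in the YFP contrast at day 90 it kept 51 of 57 (marrow) and 392 of 440 (spleen). No filter gave 5 (YFP contrast, spleen, day 5), 49, 26 and 50 (organs), 28 (days, YFP+ marrow), 11 (age, YFP- spleen), 4 and 21 (difference between days), 2 (organs) and 1 (ages, marrow). The compared groups alone gave 93, 11 and 0 (organs), 62 and 17 (days, YFP+), 11 and 10 (age, YFP+) and 0 (difference between days, spleen). DESeq2 size factors gave 10 (days, YFP+ marrow), and F-prefixed mice alone 1 (difference between ages, marrow). Without the libraries lowest in Sdc1 the counts were 4 (organs, YFP- at day 90), 0 (the same at day 5), 30 (days, YFP+ marrow) and 3 (difference between days, spleen). Of 288 list tests 92 passed, 3 with an estimated correlation, 15 with fry and 83 without the libraries lowest in Sdc1. With each library left out in turn the counts for the YFP contrast ran from 41 to 67 and 286 to 623 (day 90, marrow and spleen) and from 0 to 0 and 0 to 1694 (day 5). Those for organs ran from 10 to 24 and 5 to 29 (day 90) and from 0 to 0 and 0 to 2023 (day 5). Those for days ran from 7 to 16 and 0 to 0 (marrow, YFP+ and YFP-) and from 13 to 89 and 0 to 61 (spleen). Those for age ran from 3 to 5 and 0 to 0 (marrow) and from 0 to 5 and 0 to 275 (spleen). Those for differences ran from 2 to 3 and 3 to 121 (days), 0 to 2 (organs), 0 to 1 and 0 to 0 (ages). Of the single genes recomputed in each setting, 15 of 22 (marrow, day 90), 44 of 62 (spleen, day 90), 3 of 11 and 2 of 7 (organs, day 90) kept their call in every left-out fit. So did 4 of 14 and 12 of 22 (days, YFP+), 3 of 3 and 0 of 4 (age, YFP+), and 2 of 2 and 3 of 6 (difference between days). In simulated contrasts of 3 or 4 libraries per group edgeR recovered 6.0 to 32.8% of the genes changed by log2 1. It recovered 52.2 to 73.1% of those changed by log2 2 and 77.3 to 83.3% of those changed by log2 3. Mouse effects were simulated in 1 of these contrasts only. So 0 calls there leave changes near log2 1 open and do not exclude larger ones in single genes.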

Other observations

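The tests in this part, of splits and of 1 hypothesis, were written before their results were seen. In YFP+ spleen cells, immediate early genes (median 0.46) and mitochondrially encoded genes (0.46) were higher at day 90 than at day 5, each with an adjusted p = 0.0013 (adjusted p = 0.312 and adjusted p = 0.342 with an estimated correlation). The plasma cell identity list was lower at day 90 in YFP+ cells of marrow (-0.23, adjusted p = 0.0131) and spleen (-0.19, 0.0364), with adjusted p = 0.249 and adjusted p = 0.224 with an estimated correlation. Mki67 stood at 21.7 ± 10.4 CPM in YFP+ and 30.5 ± 14 in YFP- marrow cells at day 5, and at 28.1 ± 11.1 and 38.1 ± 18.1 in spleen, with no difference passing.

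The marrow lists of the day-90 YFP contrast not given so far held no passing member: glycolysis (median -0.08, adjusted p = 0.512), nuclear respiratory chain (-0.15, 0.134), mitochondrially encoded (-0.05, 0.786), immediate early (0.01, 0.656), NF-kB (0.09, 0.583), interferon (0.14, 0.238) and ribosomal proteins (-0.07, 0.33). For immediate early and NF-kB genes the median was positive and the mean negative (-0.06 and -0.03), and for apoptosis regulators and surface molecules the medians were 0.03 and 0.06 with means of -0.03 and -0.04. Of 4 NK cell markers 3 fell adjusted over the list alone in that contrast. Between cohorts, middle-aged YFP+ spleen cells were lower in the NF-kB (-0.37, adjusted p = 0.00273; adjusted p = 0.141 with an estimated correlation), surface (-0.20, 0.00654; adjusted p = 0.114 with an estimated correlation) and survival receptor lists (-0.35, 0.00989; adjusted p = 0.101 with an estimated correlation).

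The day-5 marrow library whose title and cell type label contradict each other held 73.8 CPM of Slamf6, 41.2 of Fam3c, 930 of H2-Ab1, 22.3 of Rab3b, 529 of Sdc1 and 24.7 of Mki67. Its sort was not assigned from these values.

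A hypothesis is that unmarked cells at day 90 resemble cells marked 5 days earlier, in the genes that part marked from unmarked cells at day 90. Genes lower in YFP+ cells were chosen in young mice and tested in middle-aged mice. In marrow, 11 such genes had a median difference of 0.11 between day-90 YFP- and day-5 YFP+ cells (random lists: -0.32 to 0.40), against -1.15 between day-90 and day-5 YFP+ cells (-0.35 to 0.24). In spleen, 83 such genes had 0.21, which is above the range of random lists (-0.14 to 0.10), against -1.12 (-0.10 to 0.07). No gene passed between day-90 YFP- and day-5 YFP+ cells in either organ. In size the values allow the hypothesis, with a small difference left in spleen. Between YFP+ and YFP- cells at day 5 the same genes had medians of 0.01 (marrow) and -0.22 (spleen). The test thus cannot tell a likeness to cells marked 5 days earlier from one to day-5 plasma cells of either sort. Mice of day 5 and day 90 differ, and those of day 90 were older when taken, so batch, age and time cannot be parted.

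Counts of passing genes were set against other splits of the same libraries into groups of the same sizes. For the YFP and organ contrasts at day 90 the splits were drawn without regard to mouse. Against such splits, the real groups stood alone in the YFP contrast at day 90. In marrow 57 genes passed against at most 7 in the other splits (1 of 100 splits gave as many, the real one). Splits that part as many pairs of a mouse gave at most 0. In spleen 440 passed against at most 58 (1 of 100, and 58 with as many pairs parted). The same held for marrow against spleen at day 90 in YFP+ (24 against 1, 1 of 100) and YFP- cells (17 against 1, 1 of 100). Taken alone, the share was under 0.05 for day 90 against day 5 in YFP+ marrow cells (17 against 7, 1 of 35). So it was for age in YFP+ marrow (3 against 1, 1 of 35) and YFP+ spleen cells (4 against 1, 1 of 35), and for the difference between days in marrow (2 against 1, 1 of 35). Shares of 1 of 100 and 1 of 35 are the smallest that these splits can give. They are not adjusted for the number of contrasts, so chance is not firmly excluded for any of these.

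Of the other splits drawn, only 6 and 8 (YFP contrast at day 90, marrow and spleen) and 7 and 5 (organs at day 90, YFP+ and YFP-) part as many pairs of a mouse as the real one, too few for a share under 0.05 among those alone. Chance cannot be excluded for day 90 against day 5 in YFP+ spleen cells, where 45 genes passed and another split gave 60 (2 of 35 gave as many), nor for the difference between days in spleen (7 against 2036; 3 of 35). All split counts come from the fit without mouse as a block. With it 91 genes passed for the difference between days in spleen, 456 for the YFP contrast in spleen at day 5 and 11 for the difference between organs, and splits were not counted in that fit. For the contrasts with 0 genes the splits decide nothing, since every split gives at least 0 (35 of 35, and 100 of 100 for the difference between organs). Among these the highest other counts were 2717 for the YFP contrast in spleen at day 5, 84 for organs in YFP+ cells at day 5, 276 and 2364 for days in YFP- cells of marrow and spleen, 0 and 0 for age in YFP- cells of marrow and spleen, and 1 for the difference between organs. In the day-5 spleen contrast, splits that part as many pairs of a mouse gave at most 527, and the split with 2717 trades the YFP+ library of 09-15 for the YFP- library of 09-29. Other splits that call 2717, 2364 and 2036 genes, where the real ones call 0, 0 and 7, point to a structure of the spleen libraries of middle-aged mice beside the groups compared. The split with 2717 parts the YFP- libraries of 07-26 and 09-01 and the YFP+ library of 09-15 from the other day-5 spleen libraries. The former held 139.7 to 321.3 CPM of Sdc1, against 624.5 to 1032.8 in the others. Their mitochondrially encoded counts were 1.21 to 1.64% (0.61 to 0.82%), and their mean log2 ribosomal protein level was 8.43 to 8.82 (7.45 to 7.56). In the day-5 spleen libraries the structure thus goes with these levels. Its source was not tested. The splits are too few for a share under 0.05 in the YFP contrast in marrow at day 5 (real 0, highest other 0; 10 of 10), for organs in YFP- cells at day 5 (real 1, highest other 1; 2 of 10), and for the difference between ages in marrow (real 0, highest other 0; 15 of 15) and spleen (real 0, highest other 1; 15 of 15).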
